A study of Mus musculus with 9 samples.

How the data were processed

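RNA levels were measured in mouse small intestinal organoids, which are epithelial structures grown in culture, on the Affymetrix Mouse Genome 430 2.0 array. This array reads each transcript through sets of short probes (probe sets) placed toward the 3 prime end. The 9 arrays were grouped by the treatment and the replicate number in their labels: 3 untreated, 3 with an inhibitor of the TGF-beta receptors at 20 uM and 3 with TGF-beta1 at 0.04 ng/mL. Per the labels, treatment lasted 5 days from day 1 and the cultures were kept for 6 days. The compound used as inhibitor, any vehicle, the culture each replicate came from and any batch are not given in the sources used here.

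Per the labels, RNA was extracted with the miRNeasy kit, then amplified and labelled with biotin by the MessageAmp Premier method for the 3 prime assay. Per the submitters' processing notes the arrays were summarised with MAS5, whose version is not given in the sources used here. The deposited values are intensities on a linear scale, 1 signal per probe set and array. MAS5 corrects each probe by its mismatch partner, which leaves dim signals noisy. The trimmed mean of the table was 349.9 on each of the 9 arrays, so the values share 1 scale set by a single factor per array. The step that set it is not described in the sources used here. Such scaling removes any difference in total RNA between cultures. Present or absent calls were not used here.

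All 9 columns of the table were used. Its 45101 probe sets were named through the platform annotation supplied with the table. Of these, 34958 had 1 gene symbol, 932 had several and 9211 were unnamed there, and 64 control probe sets were left out. The Entrez identifier was found in a mouse gene table for 34754 of the probe sets with 1 symbol, and no symbol had to be changed. Signals were turned into log2(signal + 16), so changes of genes near or below 16 are understated, and 28.9% of all values lay at or below 16. Probe sets were kept where the signal passed its array's 40th percentile on at least 3 of the 9 arrays, which left 28691. These percentiles were signals of 25.9 to 32 and are called the filter level. A gene was represented by the 1 probe set with the highest mean, and a probe set ending in _x_at only where the gene had no other. This gave 12941 genes, of which 6139 had more than 1 probe set above the filter. Among those 6139 genes, probe sets were called in both directions in 80 genes for inhibitor against untreated, 8 for ligand against untreated and 201 for ligand against inhibitor. Probe sets with several gene symbols or none were tested only as an alternative.

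Groups were compared with limma 3.58.1 in R 4.3.3. One linear model with a mean per group was fitted over the 9 arrays, with 6 residual degrees of freedom, an empirical Bayes variance that follows intensity, 2-sided tests and Benjamini-Hochberg adjustment over all genes at 0.05. The comparisons were inhibitor against untreated, ligand against untreated and ligand against inhibitor. A further contrast, the sum of both changes from untreated, tested the departure from opposite effects. A gene is said to be called, or to have risen, fallen or changed, where its adjusted p was under 0.05. Fold changes and log2 changes are on the log2(signal + 16) scale.

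The 31 gene lists hold 738 genes of cell types, pathways and responses taken from general knowledge, and 567 of these genes were tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 93 tests of 31 lists in 3 comparisons. Camera with a correlation estimated per list and fry were run beside it. For each list the members past 0.05 were counted after adjustment over all genes and after adjustment over the list alone. Lists share members. The lists, the tests, the alternatives and the rule for naming genes were chosen before the data were examined, except those named as chosen later. The rule names, per comparison, the 10 rising and 10 falling genes with the largest log2 change among called genes whose groups do not overlap. It adds up to 4 members with the smallest p per list. It also adds fixed genes: Smad7, Skil, Tgfbi, Lgr5, Olfm4, Lyz1, Muc2, Chga, Dclk1, Alpi and Mki67.

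Both comparisons with untreated share the 3 untreated arrays. Their correlation and overlap were therefore set beside 100 simulations of unchanged groups against shared controls and beside the overlap of independent lists. Array quality was described by median signal and by the 3 prime to 5 prime ratio of control probe sets for Gapdh and beta-actin, compared with an exact permutation test whose smallest 2-sided p is 0.1 for 3 against 3. The pipeline was tested on simulated data with 12941 genes and the residual spread of the arrays. Only 66 or 67 genes were changed per fold, far fewer than the real comparisons called, so the shares below need not describe recovery there. For inhibitor against untreated it recovered 73.1% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold, with 3.85% false calls. The same shares were 73.1%, 88.1% and 100% for ligand against untreated with 6.95% false calls. They were 64.2%, 89.6% and 98.5% for ligand against inhibitor with 5.08% false calls. The number of arrays, 3 per group, limits the precision of every value.

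Alternatives were offsets of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, centring each array on its median, no intensity trend and a robust variance prior. Others were the replicate number as a block, the mean of a gene's probe sets, every probe set by itself, a fit of only the 2 groups compared, a fold minimum of 1.5 and leaving out each array in turn. Genes with a single named probe set, families of genes that share a symbol stem, and the lists below the threshold that were followed across settings were chosen after seeing the data.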

Results

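RNA was profiled in organoids of mouse small intestine, closed epithelial cultures that hold stem cells beside their differentiated progeny. The 9 arrays fell into 3 groups of 3: untreated, treated with a TGF-beta receptor inhibitor at 20 uM, and treated with the ligand TGF-beta1 at 0.04 ng/mL. The comparisons ask which genes follow when the receptors are blocked and when their ligand is added. Array medians were signals of 46.1 to 57.9, and the trimmed mean was 349.9 on every array. The median SD of a gene within a group was 0.11 on the log2 scale. The first principal component held 61.8% of the variance and placed the inhibitor arrays at 39.8 to 40.9, the untreated arrays at -10.1 to -5.3 and the ligand arrays at -33.1 to -31.8. The second held 16.7% and set the untreated arrays (16.1 to 24.9) apart from both treated groups (-15 to -6.6). The labels do not say that replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical. Signals are given as mean ± SD and log2 changes as estimate ± SE, with n = 3 arrays in every group.

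Under the inhibitor, Olfm4, a secreted glycoprotein used as a marker of intestinal stem cells, fell from a signal of 12860 ± 441 to 819.5 ± 169, a log2 change of -3.96 ± 0.12. Nid1, which encodes a basement membrane protein, rose 17.6-fold from 80.3 ± 14.0 to 1669 ± 50. Of the measured cell cycle genes 31 of 35 fell, as did 18 of 21 intestinal stem cell markers and 18 of 24 goblet cell markers. Absorptive enterocyte markers rose in 27 of 38 measured members. Across all 12941 genes tested with limma, 5837 changed, 2742 higher and 3095 lower, and 2273 of them by at least 1.5-fold. The values of both groups did not overlap in 55.9% of genes, where chance gives 10%.

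The 10 rising genes taken by size included Abca1, which exports cholesterol from cells and rose 8.88-fold from 288.8 ± 72.0 to 2636 ± 85. Atp11a, a phospholipid flippase, rose by 2.81 ± 0.14, and Sptssb, a small subunit of serine palmitoyltransferase, by 2.58 ± 0.21. Fut2, a fucosyltransferase, rose by 2.36 ± 0.28, Mfhas1 by 2.58 ± 0.17 and Arhgap44 by 2.36 ± 0.18. Rtp4, Cyp1a1 and Armh4 rose from signals under the filter level, so their folds of 8.70, 7.58 and 4.93 are understated, and Arhgap44 rose from about that level (26.5 ± 6.4). Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, had a signal of 13.9 ± 5.9 in untreated and 222.9 ± 111 in inhibitor arrays. Among the 10 falling genes were the chemokines Ccl6 (-4.34 ± 0.20) and Ccl9 (-3.81 ± 0.13), and Klk1, a kallikrein protease (-3.86 ± 0.10). Ccl6, Hemgn (-3.38 ± 0.20) and Gkn3, a gastrokine (-2.86 ± 0.17), fell to signals under the filter level. Pramel29 (-3.05 ± 0.23), 9130208D14Rik (-2.91 ± 0.08), the ceramidase gene Acer1 (-2.87 ± 0.17) and the pentraxin gene Mptx1 (-2.82 ± 0.17) made up the rest, and the inhibitor signal of Acer1 (19.2 ± 8.6) also had a mean under that level.

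The inhibitor lowered the cell cycle list with a median log2 change of -0.84, with 33 of 35 members lower when adjusted over the list alone, camera adjusted p 1.4e-15 and adjusted p = 0.096 with an estimated correlation. Examples were the thymidine kinase Tk1 (-1.34 ± 0.07), the replication helicase subunits Mcm3 (-1.06 ± 0.06) and Mcm6 (-1.24 ± 0.07), and the mitotic kinesin Kif11 (-1.07 ± 0.06). Mki67, a marker of dividing cells, fell by 0.57 ± 0.08. Stem cell markers fell in 18 of 21 members and rose in 1 (19 and 1 adjusted over the list alone), with camera adjusted p 1.43e-08 and adjusted p = 0.133 with an estimated correlation. Besides Olfm4 these included Ascl2, a transcription factor of stem cells (-1.74 ± 0.09), Aqp4 (-1.38 ± 0.08) and Cdca7 (-1.19 ± 0.09), and the stem cell receptor Lgr5 fell by 0.68 ± 0.08. Wnt target genes fell in 9 of 18 members and rose in 4 (9 and 4 adjusted over the list alone), with adjusted p = 0.489 with an estimated correlation. Ccnd1 (-1.63 ± 0.06), Axin2 (-1.32 ± 0.11) and Myc (-0.74 ± 0.08) were among those that fell. Of the Notch pathway genes 10 of 20 fell and 1 rose (10 and 1 adjusted over the list alone), including Lfng (-1.78 ± 0.16), Nrarp (-0.98 ± 0.08) and the ligand Dll1 (-0.74 ± 0.07), with adjusted p = 0.114 with an estimated correlation. Without untreated replicate 3, camera's adjusted p for the Wnt list was 0.061, in a range of 0.00157 to 0.061 over its alternatives.

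Of the markers of secretory cells, those of goblet cells fell under the inhibitor in 18 of 24 members and rose in 0 (19 and 0 adjusted over the list alone), with adjusted p = 0.114 with an estimated correlation. Klk1 and Ccl6 led this list, followed by Fcgbp (-1.21 ± 0.09) and Tpsg1 (-1.42 ± 0.12). The mucin gene Muc2, also a goblet cell product, had a change of -0.18 ± 0.08 that did not pass (adjusted p 0.0693), though it did under quantile normalization (0.0262) and the 2-group fit (0.0305), in a range of 0.0262 to 0.418. Paneth cell markers fell in 6 of 15 members and rose in 1 (6 and 1 adjusted over the list alone), led by the colipase gene Clps (-1.81 ± 0.10) and Mptx1, with adjusted p = 0.449 with an estimated correlation. The lysozyme gene Lyz1 had a change of -0.36 ± 0.18 (adjusted p 0.132) on a probe set of signal 182.3 ± 60.7, and adjusted p 0.0358 without untreated replicate 2, in a range of 0.00371 to 0.568. Leaving out 1 array moved the change of Lyz1 from -0.528 to -0.121. Its brighter probe sets, at signals of 14860 and 15990 in untreated arrays, had changes of -0.40 and -0.49 (adjusted p 0.0405 and 0.0108). They end in _x_at and were passed over for that reason. Tuft cell markers fell in 7 of 18 members (7 adjusted over the list alone), with adjusted p = 0.148 with an estimated correlation, and Dclk1, a kinase marking tuft cells, fell by 1.17 ± 0.15 to about the filter level. Enteroendocrine markers showed no shift of the list (adjusted p 0.903), with 7 of 27 higher and 8 lower (7 and 8 adjusted over the list alone). Their mean log2 change (-0.01) and camera's test differed in sign. The hormone genes Gcg (0.71 ± 0.08) and Sst (0.50 ± 0.09) rose, and Nkx2-2, a transcription factor, fell by 0.62 ± 0.10. Chga, a granule protein, had a change of -0.29 ± 0.12 (adjusted p 0.0679) and passed without untreated replicate 1 (adjusted p 0.00446, range 0.00446 to 0.282). Leaving out 1 array moved its change from -0.437 to -0.17.

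Absorptive enterocyte markers rose in 27 of 38 members and fell in 1 (29 and 1 adjusted over the list alone), with camera adjusted p 2.62e-10 and adjusted p = 0.153 with an estimated correlation. The brush border peptidases Anpep (1.90 ± 0.09), Dpp4 (1.33 ± 0.07) and Mep1b (1.07 ± 0.07) and the keratin Krt20 (1.09 ± 0.07) rose. Alpi, intestinal alkaline phosphatase, had a change of -0.13 ± 0.10 that did not pass (adjusted p 0.29). Drug and bile acid response genes rose in 14 of 20 members and fell in 1 (15 and 1 adjusted over the list alone), including the cytochromes Cyp2c55 (1.75 ± 0.08), Cyp3a13 (1.25 ± 0.07) and Cyp2b10 (1.37 ± 0.09), with adjusted p = 0.114 with an estimated correlation. Fetal-like and regeneration genes rose in 13 of 18 members and fell in 2 (14 and 2 adjusted over the list alone), led by Sprr1a (1.93 ± 0.14) and Il1rn (1.99 ± 0.16), with adjusted p = 0.406 with an estimated correlation. Genes of p53 and apoptosis rose in 14 of 23 members and fell in 1 (14 and 1 adjusted over the list alone), including Ccng1 (0.86 ± 0.07) and Plk2 (1.08 ± 0.10), with adjusted p = 0.096 with an estimated correlation. Interferon response genes rose in 11 of 20 members and fell in 1 (12 and 1 adjusted over the list alone), including the transcription factor Irf7 (1.23 ± 0.10) and Oasl2 (1.74 ± 0.18), with adjusted p = 0.252 with an estimated correlation. Extracellular matrix and adhesion genes rose in 12 of 25 members and fell in 5 (12 and 5 adjusted over the list alone), with adjusted p = 0.259 with an estimated correlation. Besides Nid1, Plat, a plasminogen activator, rose by 1.78 ± 0.14 and the laminin chain Lamb3 by 0.70 ± 0.07.

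Under the inhibitor 4 further response lists shifted up with the preset correlation. Aryl hydrocarbon receptor and NRF2 targets rose in 9 of 17 members and fell in 1 (9 and 1 adjusted over the list alone), including the sulfiredoxin gene Srxn1, with camera adjusted p 0.0296 and adjusted p = 0.362 with an estimated correlation. That call was lost without untreated replicate 3 (0.0806) or inhibitor replicate 2 (0.056), in a range of 0.00956 to 0.0806. Genes of PPAR and fatty acid oxidation rose in 10 of 24 members and fell in 1 (10 and 1 adjusted over the list alone), including the fatty acid transporter gene Cd36 (1.48 ± 0.15), with adjusted p = 0.544 with an estimated correlation. Camera's adjusted p for it was 0.0309, and it was lost without untreated replicate 3 (0.0742) and with the filter at the 60th percentile (0.0526), in a range of 0.0134 to 0.0742. Cholesterol biosynthesis genes rose in 8 of 19 members and fell in 1 (8 and 2 adjusted over the list alone), including Tm7sf2 (0.65 ± 0.08) and Insig1 (0.52 ± 0.07), with adjusted p = 0.435 with an estimated correlation. Their adjusted p of 0.0258 was 0.0705 without untreated replicate 1, in a range of 0.0127 to 0.0705. Genes responding to EGF and ERK rose in 12 of 24 members and fell in 4 (13 and 5 adjusted over the list alone), including Errfi1, a feedback inhibitor of the EGF receptor (1.03 ± 0.07), with adjusted p = 0.343 with an estimated correlation. Their adjusted p of 0.0259 was 0.066 without untreated replicate 1 and 0.0526 with the filter at the 60th percentile, in a range of 0.00975 to 0.066.

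The known targets of the pathway itself did not shift as a list under the inhibitor. Of 21 measured TGF-beta target genes 4 rose and 4 fell (4 and 3 adjusted over the list alone), with camera adjusted p 0.593. Pmepa1, a feedback inhibitor of the pathway, fell by 1.14 ± 0.11, while the cell cycle inhibitors Cdkn2b (0.85 ± 0.09) and Cdkn1a (0.43 ± 0.09) and the GTPase Rhob (1.13 ± 0.13) rose. Skil, a transcriptional repressor induced by the pathway, had a change of 0.01 ± 0.08 (adjusted p 0.949) and Tgfbi of 0.09 ± 0.16 (adjusted p 0.672). The inhibitory Smad gene Smad7 fell by 0.39 ± 0.15 with adjusted p 0.0462. This did not pass without untreated replicate 1 (0.0875), untreated replicate 3 (0.181), inhibitor replicate 2 (0.0731) or inhibitor replicate 3 (0.209, with a change of -0.24). It was also lost with the replicate block (0.0632), the 2-group fit (0.0584), no filter (0.0833), quantile normalization (0.0851), median centring (0.0756), no intensity trend (0.0699) and the mean of probe sets (0.079), in a range of 0.0177 to 0.209. Of the 10 measured BMP target genes, which report a sister pathway, Id1 (-1.34 ± 0.10), Id2 (-0.86 ± 0.13), Id3 (-1.46 ± 0.15) and Smad6 (-1.60 ± 0.17) fell and 1 rose (4 and 1 adjusted over the list alone), with no call for the list (adjusted p 0.247). The inhibitor signal of Smad6 had a mean under the filter level.

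Centring the arrays on their medians turned the balance of the inhibitor calls from 47% higher to 57.9% higher (3285 higher, 2389 lower). The 3 prime to 5 prime log2 ratio of beta-actin was 0.211 ± 0.03 in inhibitor arrays and 0.411 ± 0.035 in untreated arrays, with an exact permutation p of 0.1, the smallest that 3 against 3 can give, while Gapdh was at -0.278 and -0.265 (exact p 0.3). Among markers of cells outside the epithelium, the fibroblast, leukocyte and endothelial lists were not called (camera adjusted p 0.851, 0.934 and 0.903). Only 8 of 20, 8 of 24 and 6 of 15 members of these lists were tested, while 12, 15 and 9 lay under the filter. The neuronal and glial list had 2 of 6 members higher (2 adjusted over the list alone) with adjusted p 0.0878, and 0.0411 without untreated replicate 3, in a range of 0.0411 to 0.302.

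**Figure D1:**
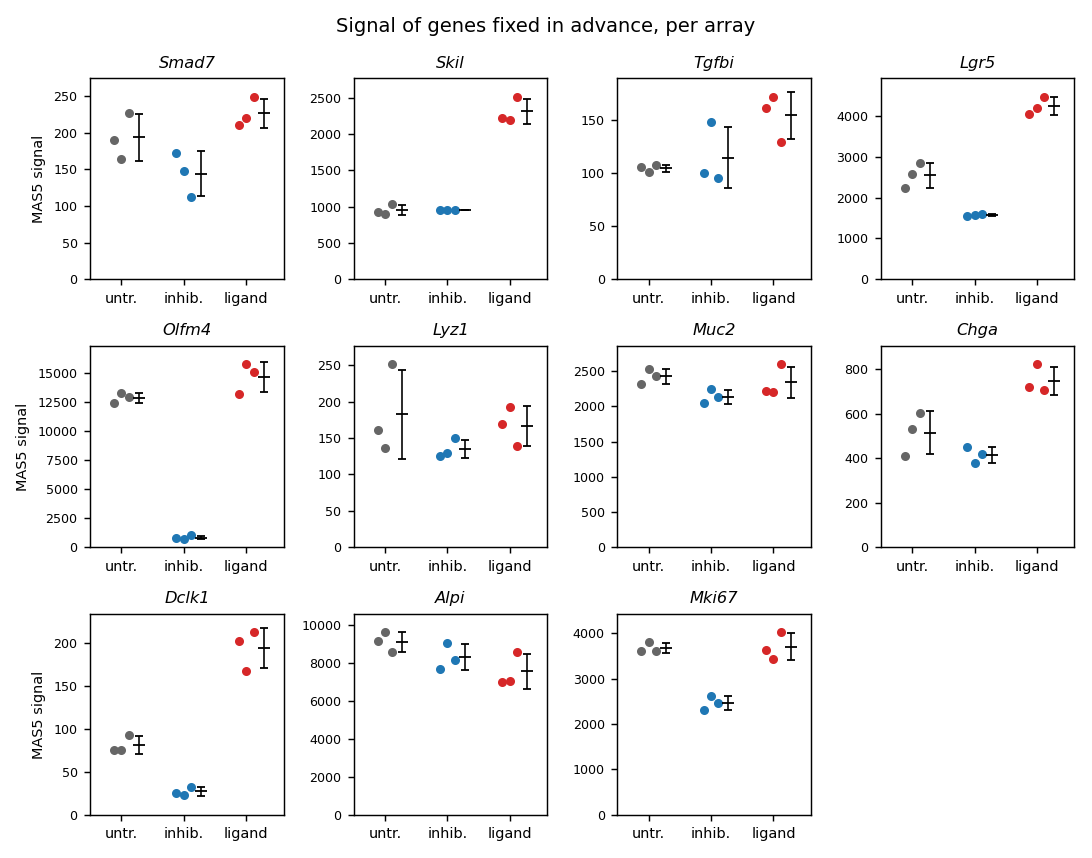
MAS5 signal (y axis, linear) of the genes fixed in advance in untreated, inhibitor and ligand arrays; points are single arrays and the black marks are mean ± SD of 3 arrays. Olfm4 lies near 819.5 in the inhibitor group against 12860 untreated, and Skil near 2311 in the ligand group against 951.8 untreated.

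With the ligand, Cym, which encodes the milk-clotting protease chymosin, rose from a signal of 30.2 ± 8.6, about the filter level, to 14290 ± 1100. With 16 added to each signal this is 313-fold, a value set partly by that offset. Clu, a secreted chaperone, rose 25.1-fold from 95.8 ± 38.5 to 2702 ± 343. Of 21 measured TGF-beta target genes 12 rose and 2 fell, and of 21 stem cell markers 14 rose and 0 fell. Absorptive enterocyte markers fell in 27 of 38 measured members and drug and bile acid response genes in 17 of 20. In all, 3123 genes changed, 1911 higher and 1212 lower, 1109 of them by at least 1.5-fold, and the groups did not overlap in 38.6% of genes against 10% by chance.

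Further genes that rose most with the ligand were Cfi, a complement protease (8.61-fold, 214.9 ± 17.3 to 1971 ± 97.6), the chloride channel Ano1 (2.59 ± 0.22), the RNA-binding protein gene Rbms3 (2.92 ± 0.15) and Gkn3 (2.55 ± 0.17). Fstl1, Lect2, Scara3 and Dynap rose from untreated signals under the filter level, so their folds of 14.0, 8.12, 6.34 and 5.88 are understated, and Rbms3 rose from about that level (29.1 ± 4.4). The largest falls were those of the adhesion receptor Adgrd1 (-2.43 ± 0.19) and the retinol-binding protein Rbp7 (-2.17 ± 0.16). The cytochromes Cyp2d34 (-2.10 ± 0.17) and Cyp2d10 (-2.04 ± 0.16), the esterase Ces1f (-1.66 ± 0.15), the arginase Arg2 (-1.70 ± 0.11) and the transaminase Abat (-1.69 ± 0.15) also fell. So did the sialidase Neu3 (-1.84 ± 0.15), Zg16, a lectin of goblet cells (-1.77 ± 0.18), and the dynein chain Dnah2 (-1.61 ± 0.14).

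The TGF-beta target list shifted up with the ligand (camera adjusted p 0.00217), with 13 members higher and 3 lower when adjusted over the list alone, and adjusted p = 0.201 with an estimated correlation. The matricellular genes Ccn1 (1.68 ± 0.09) and Ccn2 (2.24 ± 0.20), Skil (1.27 ± 0.08) and Pmepa1 (1.55 ± 0.11) led it, and the untreated signal of Ccn2 was about the filter level. Smad7 had a change of 0.22 ± 0.15 that did not pass (adjusted p 0.331). Tgfbi rose by 0.49 ± 0.16 (adjusted p 0.0359). That call was lost without untreated replicate 1 (0.0812), 2 (0.0971) or 3 (0.0659) and without ligand replicate 1 (0.102) or 2 (0.121). It was also lost under median centring (0.0895), quantile normalization (0.098) and no filter (0.0718), and its adjusted p ranged from 0.0108 to 0.121 over the alternatives. Epithelial-mesenchymal transition genes rose in 3 of 10 members (3 adjusted over the list alone), led by Fstl1, with adjusted p 0.0451 and adjusted p = 0.174 with an estimated correlation. That list call was lost without untreated replicate 2 (0.051), ligand replicate 2 (0.104) or ligand replicate 3 (0.0597), with an offset of 1 (0.0627) and with no filter (0.134), in a range of 0.015 to 0.134. Extracellular matrix and adhesion genes rose in 14 of 25 members (16 higher and 1 lower adjusted over the list alone), including the laminin chains Lama3 (1.65 ± 0.15) and Lama5 (0.79 ± 0.12), with adjusted p = 0.155 with an estimated correlation. Genes responding to EGF and ERK rose in 14 of 24 members and fell in 1 (15 and 2 adjusted over the list alone), including Jun (1.40 ± 0.10), with adjusted p = 0.152 with an estimated correlation.

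Stem cell markers rose in 14 of 21 members with the ligand (15 higher and 1 lower adjusted over the list alone), including the Wnt feedback ligase gene Rnf43 (1.42 ± 0.10), Ephb3 (1.30 ± 0.11), Ascl2 (1.13 ± 0.09) and Lgr5 (0.74 ± 0.08). Camera gave adjusted p 2.06e-09, and adjusted p = 0.114 with an estimated correlation. Olfm4 itself had a change of 0.18 ± 0.12 that did not pass (adjusted p 0.295). Wnt target genes rose in 13 of 18 members (13 adjusted over the list alone), including the transcription factor gene Sp5 (1.92 ± 0.16), with adjusted p = 0.114 with an estimated correlation. Notch pathway genes rose in 8 of 20 members (10 adjusted over the list alone), including Notch1 (0.82 ± 0.13), with adjusted p = 0.096 with an estimated correlation. Fetal-like and regeneration genes rose in 13 of 18 members (14 higher and 1 lower adjusted over the list alone), led by Clu and Anxa1 (2.18 ± 0.19), with adjusted p = 0.211 with an estimated correlation. Cell cycle genes rose in 8 of 35 members and fell in 6 (8 and 6 adjusted over the list alone), with no call for the list (adjusted p 0.922) and a median and test that differed in sign. Mki67 had a change of 0.01 ± 0.08 (adjusted p 0.963).

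Enteroendocrine markers rose in 15 of 27 members and fell in 1 (18 and 1 adjusted over the list alone), with adjusted p = 0.202 with an estimated correlation. The incretin hormone gene Gip rose by 0.91 ± 0.09, the progenitor factor Neurog3 by 0.67 ± 0.11 and Chga by 0.54 ± 0.12. Tuft cell markers rose in 8 of 18 members (9 adjusted over the list alone), including Dclk1 (1.11 ± 0.15), Avil (1.06 ± 0.13) and Rgs13 (1.53 ± 0.21), with adjusted p = 0.096 with an estimated correlation. Goblet cell markers rose in 8 of 24 members and fell in 2 (9 and 2 adjusted over the list alone), and the list was not called (adjusted p 0.245). Muc2 (-0.06 ± 0.08, adjusted p 0.643) and Lyz1 (-0.09 ± 0.18, adjusted p 0.775) did not pass.

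Absorptive genes fell with the ligand, with 32 of 38 enterocyte markers lower and 1 higher when adjusted over the list alone, camera adjusted p 5.89e-19 and adjusted p = 0.096 with an estimated correlation. The sugar transporters Slc2a2 (-1.58 ± 0.10) and Slc2a5 (-1.30 ± 0.10), the peptidase Enpep (-1.23 ± 0.10) and the acyltransferase Mogat2 (-1.05 ± 0.09) fell. Alpi had a change of -0.28 ± 0.10 (adjusted p 0.0571) and passed without ligand replicate 3 (0.00619), under quantile normalization (0.0175) and under median centring (0.044), range 0.00619 to 0.177. Drug and bile acid response genes (17 of 20 lower adjusted over the list alone) included the sulfotransferase Sult1b1 (-0.88 ± 0.07) and the nuclear receptor Nr1i3 (-1.24 ± 0.14), with adjusted p = 0.096 with an estimated correlation. Genes of PPAR and fatty acid oxidation fell in 16 of 24 members and rose in 1 (17 and 1 adjusted over the list alone), including the thiolase Acaa1b (-1.51 ± 0.15) and the coactivator Ppargc1a (-0.90 ± 0.10), with adjusted p = 0.114 with an estimated correlation. Aryl hydrocarbon receptor and NRF2 targets fell in 10 of 17 members (10 adjusted over the list alone), including Cbr3 (-1.41 ± 0.10) and the glutathione transferase Gsta2 (-1.32 ± 0.13), with adjusted p = 0.096 with an estimated correlation. Cholesterol biosynthesis genes fell in 4 of 19 members and rose in 1 (5 and 1 adjusted over the list alone), including Insig1 (-0.55 ± 0.07), with adjusted p = 0.252 with an estimated correlation. Hypoxia and glycolysis genes fell in 5 of 21 members and rose in 1 (6 and 1 adjusted over the list alone), including Pfkp (-0.36 ± 0.07), with adjusted p = 0.411 with an estimated correlation. Unfolded protein and integrated stress response genes fell in 4 of 26 members and rose in 1 (4 and 1 adjusted over the list alone), including Trib3 (-0.64 ± 0.09), with adjusted p = 0.111 with an estimated correlation. The adjusted p of this last list was 0.00844, and 0.0525 under quantile normalization, where the call was lost (range 0.00344 to 0.0525). Median centring moved the median change of all genes from 0.05 to -0.06 and turned the ligand calls from 61.2% higher to 36.4% higher (1051 higher, 1838 lower). Changes of the size of that shift have no settled direction.

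**Figure D2:**
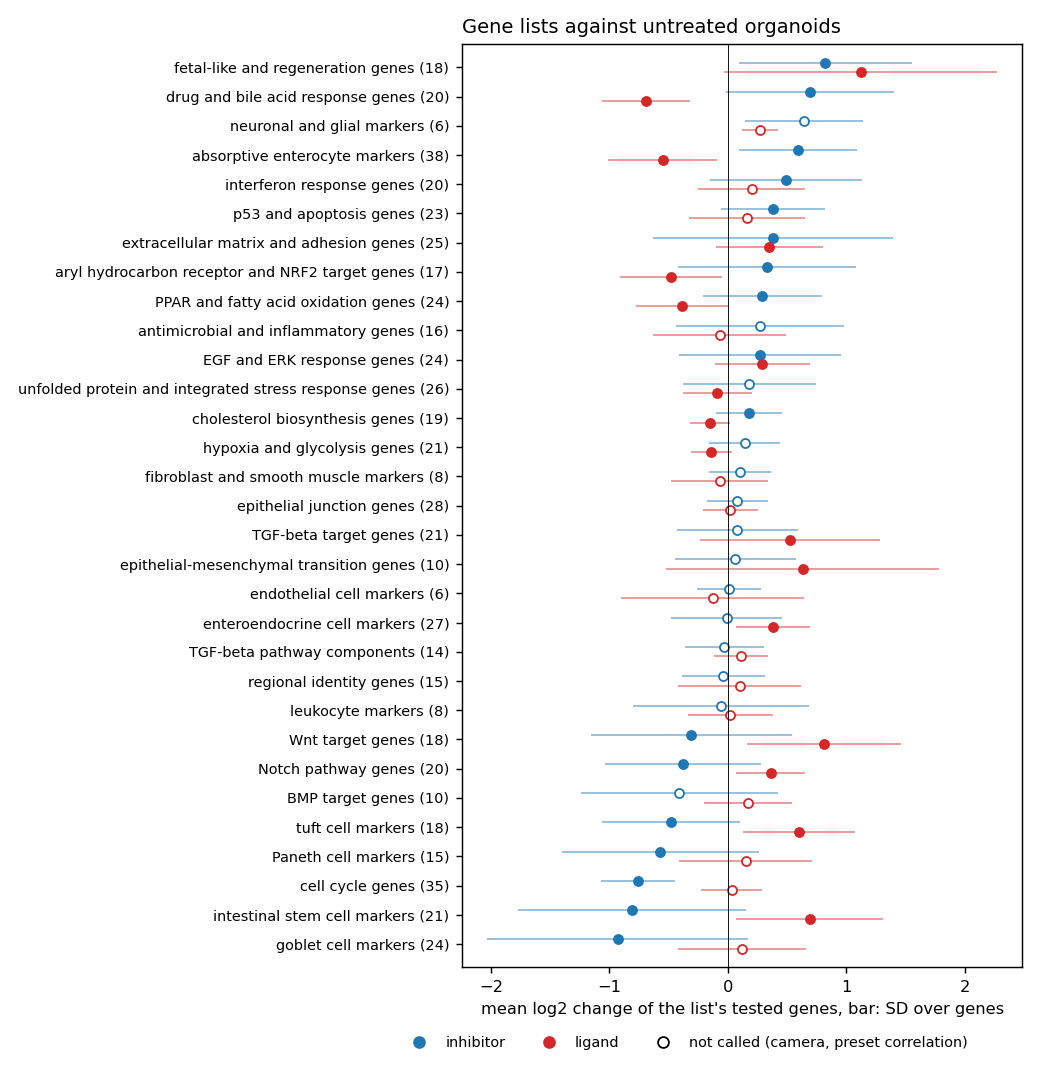
Mean log2 change (x axis) of the tested members of each of the 31 lists against untreated arrays, for the inhibitor (blue) and the ligand (red); bars are the SD over genes, open points were not called by camera with the preset correlation, and the number of tested genes follows each name. Stem cell markers lie at -0.81 with the inhibitor and 0.69 with the ligand, and absorptive enterocyte markers at 0.59 and -0.55.

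Set directly against each other, the ligand and inhibitor groups differed most in Cym (275-fold higher with the ligand), Gkn3 (42.3-fold), Ccl6 (36.4-fold) and Pcdh8, a protocadherin (24.6-fold). Gkn3 and Ccl6 lay under the filter level in inhibitor arrays, and Cym and Pcdh8 about it, so these folds depend on the offset. Nid1 was 20.3-fold lower with the ligand, Cyp2d10 12.6-fold and Reg3g, an antibacterial lectin, 10.5-fold. All 21 stem cell markers were higher with the ligand (21 adjusted over the list alone) and 35 of 38 enterocyte markers lower (36 adjusted over the list alone). In all, 7186 of 12941 genes differed, 4214 higher and 2972 lower with the ligand, 3484 of them by at least 1.5-fold, and the groups did not overlap in 60.6% of genes against 10% by chance.

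Between these groups Olfm4 differed by 4.15 ± 0.12, Ascl2 by 2.87 ± 0.09 and Lgr5 by 1.42 ± 0.08, and the stem cell list had adjusted p = 0.114 with an estimated correlation. Cell cycle genes were higher with the ligand in 31 of 35 members (31 adjusted over the list alone), with Mcm2 at 1.40 ± 0.07 and Mki67 at 0.58 ± 0.08, and adjusted p = 0.096 with an estimated correlation. Goblet cell markers were higher in 17 of 24 members and lower in 1 (17 and 2 adjusted over the list alone), including the transcription factor Atoh1 (1.89 ± 0.12), with adjusted p = 0.163 with an estimated correlation. Tuft cell markers were higher in 13 of 18 members (13 adjusted over the list alone), with Dclk1 at 2.28 ± 0.15 and adjusted p = 0.096 with an estimated correlation. Enterocyte markers, with Anpep at -2.32 ± 0.09 and Dpp4 at -1.74 ± 0.07, had adjusted p = 0.0986 with an estimated correlation. Drug and bile acid response genes were lower in 18 of 20 members and higher in 1 (18 and 1 adjusted over the list alone), with Ces2a at -2.68 ± 0.11 and adjusted p = 0.096 with an estimated correlation. TGF-beta target genes were higher in 11 of 21 members and lower in 6 (12 and 6 adjusted over the list alone), with Pmepa1 at 2.69 ± 0.11 and Cdkn2b at -1.47 ± 0.09, and the list was not called (adjusted p 0.271). Smad7 was higher with the ligand by 0.61 ± 0.15, Skil by 1.26 ± 0.08 and Chga by 0.83 ± 0.12, while Lyz1 (0.27 ± 0.18), Muc2 (0.13 ± 0.08) and Alpi (-0.14 ± 0.10) did not pass (adjusted p 0.237, 0.189 and 0.244). Muc2 passed under quantile normalization (0.0279, range 0.0279 to 0.655). The brighter probe sets of Lyz1, which end in _x_at, were higher with the ligand by 0.45 and 0.56 (adjusted p 0.0165 and 0.00303). The mean of its probe sets, which includes these, was higher by 0.43 (adjusted p 0.00213, range 0.00213 to 0.722). Alpi passed without ligand replicate 3 (0.0279) and under median centring (0.0454), range 0.0279 to 0.581, and leaving out 1 array moved its difference from -0.237 to -0.078. Tgfbi was higher by 0.40 ± 0.16 (adjusted p 0.0437). It was not called without inhibitor replicate 1 (0.14) or 3 (0.169) or ligand replicate 1 (0.115) or 2 (0.146). Quantile normalization (0.284), median centring (0.25), no filter (0.0819), the 2-group fit (0.0632) and no intensity trend (0.051) ended that call too, range 0.00515 to 0.284. Median centring moved the median difference of all genes from 0.066 to -0.117 and the calls from 58.6% higher to 38.9% higher (2752 higher, 4318 lower), so differences of that size have no settled direction. The 3 prime to 5 prime log2 ratio of beta-actin was 0.468 ± 0.099 in ligand and 0.211 ± 0.03 in inhibitor arrays and the array median 54.8 ± 3.2 and 47.5 ± 1.7, each with an exact permutation p of 0.1, the smallest possible.

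Across the 12941 genes the changes under inhibitor and ligand had a Pearson r of -0.0511 and a Spearman's rho of -0.0843, where genes are not independent replicates. The sign of r changed between settings, and leaving out 1 array gave -0.0552 (without ligand replicate 3) to 0.0287 (without untreated replicate 3). The r of -0.0511 lies below the mean r of 0.499 (0.471 to 0.522) that unchanged groups gave when simulated against the shared untreated arrays. Those groups hold no effects, and real effects of any kind change r, so this gap in r decides nothing. The covariance was -0.00954 against 0.0107 simulated, a difference of -0.0203. Both comparisons called 1842 genes. Of these 657 fell with the inhibitor and rose with the ligand, where independent lists would share 457, and 567 did the opposite, where 257 would be shared. Another 412 rose under both (405 for independent lists) and 206 fell under both (290). The simulations called 0 genes in both in the same direction, and since 3 controls cannot be split, part of the same-direction genes may come from the shared controls. Error in these moves both changes the same way, so for genes that neither treatment changes it does not add to the opposite classes. Where only 1 treatment changes a gene, such error can still place it there, so those counts are not free of it.

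Genes chosen after their values were seen illustrate both classes. Gkn3 changed by -2.86 ± 0.17 with the inhibitor and 2.55 ± 0.17 with the ligand, Pcdh8 by -2.82 ± 0.16 and 1.80 ± 0.16, and Cyp2d10 by 1.62 ± 0.16 and -2.04 ± 0.16. Both treatments raised Clu (1.67 ± 0.18 and 4.65 ± 0.18), Anxa1 (1.52 ± 0.19 and 2.18 ± 0.19), Tnfrsf19, a receptor of the TNF family (1.46 ± 0.23 and 2.44 ± 0.23), and Ly6d (1.78 ± 0.21 and 1.61 ± 0.21). Tnfrsf19 was the only member of the stem cell list that rose with the inhibitor. Both treatments lowered Rbp7 (-1.50 ± 0.16 and -2.17 ± 0.16), the alcohol dehydrogenase Adh4 (-2.67 ± 0.14 and -1.28 ± 0.14), and Fbp1, an enzyme of gluconeogenesis (-1.01 ± 0.10 and -1.06 ± 0.10). The contrast of departure from opposite effects passed for 3083 genes, 1650 with a positive and 1433 with a negative sum. That count was 2025 without untreated replicate 2. The contrast can also pass for genes that only 1 treatment changed, or that changed by unequal opposite amounts. Its count is therefore not one of genes that moved the same way, of which 618 were called in both comparisons.

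**Figure D3:**
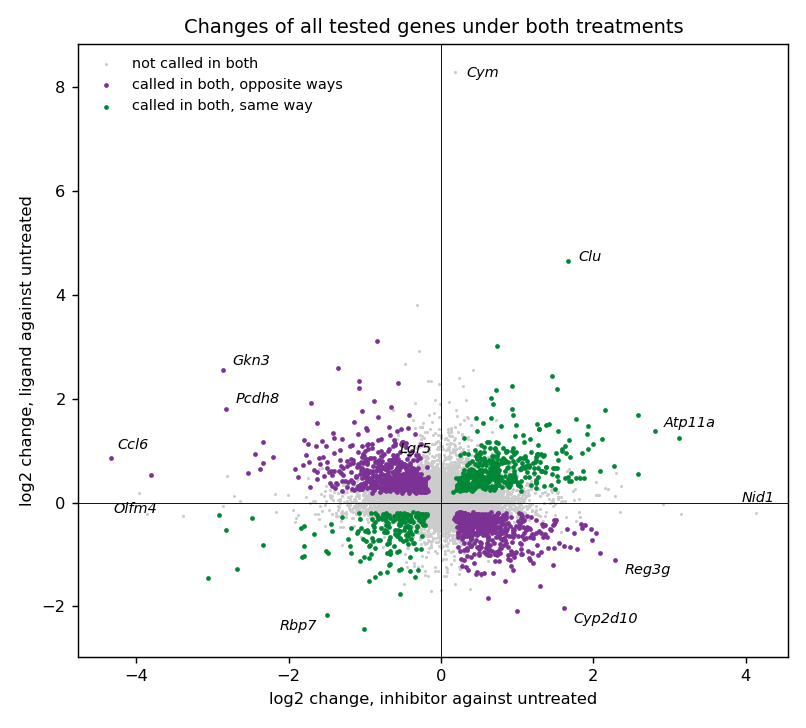
Log2 change of each of the 12941 tested genes with the inhibitor (x axis) and with the ligand (y axis) against the same untreated arrays; purple points were called in both comparisons in opposite directions (1224 genes), green points in the same direction (618 genes), and grey points were not called in both. Cym and Olfm4 stand far out on 1 axis each, and Clu is high on both.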

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

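The tests on RNA integrity, on batch or vehicle, on the number of stem cells, on Notch activity and on enterocyte maturity were chosen only after the results were seen.

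Among the probe sets without a single gene name, 4767 passed the filter, and 1187 of them changed under the inhibitor, 315 higher and 872 lower. With the ligand 456 changed, 316 higher and 140 lower, and between ligand and inhibitor 1837 differed, 1436 higher and 401 lower with the ligand (limma, adjusted p under 0.05). Under the inhibitor the largest rises among them were 2.59 ± 0.13 and 2.48 ± 0.21 and the largest falls -2.83 ± 0.10 and -2.53 ± 0.19. These probe sets are not part of the gene counts.

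Regrouping the arrays set the counts of changed genes beside those of other groupings. In each comparison 1 of the 10 splits of the 6 arrays, the real one, called as many genes: 5837 for inhibitor against untreated, 3123 for ligand against untreated and 7186 for ligand against inhibitor, with 0 as the highest count of any other split. So few splits cannot give a small p. Every other split of the 6 arrays also mixes both groups, so that any large difference between them enters the spread. Few calls are then likely whatever the cause of the difference, and the 0 says little about the counts. For the departure from opposite effects 4 of 100 drawn splits of the 9 arrays reached the real 3083 genes, with 5789 as the highest of the others. The other 3 had the inhibitor arrays in the place of the untreated ones, and 1097 was the highest count with arrays of different groups in that place.

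Both treatments moved 618 genes in the same direction from untreated, among them Clu, Anxa1 and Rbp7, although 1 blocks the receptors and the other adds their ligand. Error of the 3 untreated arrays shared by both comparisons could give or enlarge this set and stays open: simulated unchanged groups gave 0 genes called in both comparisons in any direction, so the bound set in advance decides nothing. Independent lists would already share 405 rising and 290 falling genes against the 412 and 206 seen, and the count was 412 without untreated replicate 1, 414 without replicate 2 and 634 without replicate 3, in fits with fewer arrays. Scaling of the arrays left 570 under median centring and 619 under quantile normalization, and of the control genes 0 had 3 prime to 5 prime ratios of the untreated arrays all to one side of the treated arrays, which argues against scaling and RNA integrity. A day, batch or vehicle that sets the untreated cultures apart stays open, since the labels give 0 batches that hold untreated and treated arrays.

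Olfm4 fell further under the inhibitor than the other stem cell markers, with a change -5.12 SD from the median of the other 20 (-0.65, SD 0.65, from -1.74 to 1.46). That distance is the pattern itself, so it does not decide whether fewer stem cells alone could be the cause, and this stays open. Olfm4 is also induced by Notch, and lower Notch activity alone would likely raise Atoh1, which Notch represses. Atoh1 changed by -1.32 ± 0.12, and goblet cell markers fell (camera adjusted p = 0.114 with an estimated correlation). So mainly Atoh1 argues against lower Notch activity as the whole cause. Lower Notch activity stays open as a part, since Nrarp (-0.98) and Lfng (-1.78) fell. Of the Notch pathway list 10 of 20 genes fell (camera adjusted p = 0.114 with an estimated correlation). Atoh1 is among those 10, so that count does not measure Notch activity. A direct need of Olfm4 for signalling through the receptors was not tested.

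Cyp1a1 rose under the inhibitor from a signal under the filter level. Action of the inhibitor on the aryl hydrocarbon receptor could raise it, and of the receptor's other targets Tiparp and Nqo1 only 1 rose: Tiparp by 0.32 ± 0.08 (adjusted p 0.00468), while Nqo1 fell by 0.58 ± 0.10 on the log2 scale (adjusted p 0.000449). This test cannot tell, and Tiparp was looked up for it outside the naming rule. More mature enterocytes may carry more Cyp1a1, and this stays open as well. Its change lay 4.75 SD above the median of the 38 enterocyte markers (0.55, SD 0.5), but the gene was named for the size of its rise, so that distance decides nothing.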

How the results depend on the processing

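The setting with only single named probe sets and the choice of uncalled results followed across settings came after the results were seen.

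Of 359 called changes of named genes 341 held in every alternative run for single genes, 18 were lost in at least 1 and 0 reversed. The fold minimum and the fit of all probe sets were not among these. Most of these genes were named for large changes or small p in the same data, so their share does not speak for all calls. Of all 3123 ligand calls 3059 held with an offset of 1, but 2263 under median centring and 2172 without untreated replicate 1. Of the 7186 calls between ligand and inhibitor 5724 held under median centring. Of 50 called list shifts 40 held under the other offsets, filters and scalings, the replicate block and each array left out, the only fits run for lists besides the estimated correlation, under which 0 held (adjusted p 0.096 to 0.544), and 49 passed fry in the same direction. Fry also passed some lists that camera did not call, such as BMP target genes (fry adjusted p 0.0021) and antimicrobial and inflammatory genes (0.00123) under the inhibitor. It therefore adds little to these calls. The loss of every call with an estimated correlation need not come from correlated members. For tuft cell markers with the ligand the estimate was -0.01, under the preset 0.01, yet camera's unadjusted p rose from 0.000131 to 0.0061. For Notch pathway genes with the ligand it was -0.049, and p rose from 0.000743 to 0.0103. Other estimates lay above the preset, such as 0.226 for absorptive enterocyte markers, where correlation may count as well.

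Asking for at least 1.5-fold left 2273 genes for inhibitor against untreated, 1109 for ligand against untreated and 3484 for ligand against inhibitor, by construction fewer. All probe sets by themselves gave 10060 and 13544 for inhibitor against untreated and ligand against inhibitor, since more were tested. Genes with a single named probe set only, fewer by construction, gave 2664, 1458 and 3350, and 1426 for the departure. The departure ranged from 2025 without untreated replicate 2 to 3408 without ligand replicate 3. The fit with replicate number as a block gave 5759, 3007, 7152 and 2978, with correlations of same-number pairs from -0.08 to 0.07. The cause of the changes given next was not tested.

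The correlation of inhibitor and ligand effects (-0.0511) was 0.00952 with an offset of 1, -0.112 with an offset of 64, 0.00143 with no filter, -0.114 with the filter at the 60th percentile and -0.0176 with single named probe sets. It ran from -0.0552 without ligand replicate 3 to 0.0287 without untreated replicate 3. These values lie on both sides of 0 and all below 0.471, the lowest r simulated for unchanged groups with shared controls. The simulations were run for the main setting only and hold no real effects, so lying below them decides nothing.

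Reversals were limited to results that had not passed, and for lists they are turns in the sign of camera's test. With no filter the ligand value of Cd8a was -0.248. The inhibitor shift of endothelial cell markers was then 0.054, against 0.01 in the main fit, so only the sign of camera's test turned. The inhibitor shift of fibroblast and smooth muscle markers was -0.257 at the 60th percentile. For cell cycle genes the ligand shift was 0.03 under quantile normalization and also 0.03 in the main fit, so only the sign of camera's test turned. Median centring gave -0.103 for Mki67 with the ligand and -0.058 for Muc2 between ligand and inhibitor. The mean of probe sets gave -0.172 for Skil under the inhibitor and 0.014 for Lyz1 with the ligand.

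Leaving out 1 array moved the inhibitor values of Skil from -0.033 to 0.069, Tgfbi from -0.084 to 0.193 and Cldn5 from -0.068 to 0.39. It moved the ligand values of Lyz1 from -0.262 to 0.146, Mki67 from -0.056 to 0.058, Eng from -0.389 to 0.001 and Gfap from -0.036 to 0.701. Inhibitor shifts ran from -0.052 to 0.035 for enteroendocrine cell markers and from -0.107 to 0.09 for endothelial cell markers. Ligand shifts ran from 0.003 to 0.049 for cell cycle genes and from -0.095 to 0.175 for leukocyte markers. Those of the cell cycle genes stayed above 0, and only the sign of camera's test turned.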

Other observations

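The families of genes described here were tested only after the results were seen, and no explanation of them was tested.

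Genes of drug and lipid metabolism were grouped by family, with some members that belong to the lists as well, and with the ligand none of the 16 families tested passed with an estimated correlation (smallest adjusted p 0.0612). All 6 measured Cyp2d genes, 7 of 8 Cyp2c genes and 7 of 12 carboxylesterases fell, with median log2 changes of -1.42, -0.86 and -0.92. These families hold cytochromes and esterases that act on drugs, steroids and lipids. UDP-glucuronosyltransferases, which couple sugar to such compounds, fell in 5 of 6 members, and glutathione transferases fell in 9 of 19 and rose in 1. Camera with an estimated correlation gave adjusted p of 0.108, 0.0612, 0.128, 0.0612 and 0.212 for these 5 families in that order. Genes of oxidative phosphorylation fell in 16 of 87 members (median -0.17), with the smallest preset camera adjusted p, 1.48e-09, and adjusted p = 0.46 with an estimated correlation. Under quantile normalization and median centring the medians of the Cyp2d genes were -1.51 and -1.53. With the inhibitor 6 of 8 Cyp2c genes rose and 1 fell (median 0.55, adjusted p 0.108 with an estimated correlation). Ribosomal protein genes fell in 17 of 46 members under the inhibitor, in 23 under quantile normalization and in 9 under median centring, with adjusted p = 0.572 with an estimated correlation.

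Several genes outside the lists, chosen after their values were seen, moved in opposite directions. The serotonin receptor gene Htr4 changed by -1.71 ± 0.19 with the inhibitor and 1.91 ± 0.19 with the ligand, with an inhibitor signal under the filter level, so that its fall is understated. Fgfr2, a fibroblast growth factor receptor, changed by -1.42 ± 0.11 and 1.35 ± 0.11. The ribonuclease gene Rnase1 changed by -1.80 ± 0.13 and 1.20 ± 0.13. Bst1, an enzyme that makes cyclic ADP-ribose, rose by 1.21 ± 0.14 and had a change of -1.16 ± 0.14 with the ligand, and the secreted factor gene Fam3b changed by 1.47 ± 0.10 and -1.21 ± 0.10. Alcohol dehydrogenase Adh7 fell under both (-1.17 ± 0.24 and -0.97 ± 0.24), as did the water channel gene Aqp3 (-1.07 ± 0.18 and -1.13 ± 0.18).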
